A study of Mus musculus with 16 samples.

How the data were processed

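Small RNAs were measured on 16 one-colour arrays hybridised with Cy3-labelled RNA from Balb/c mouse bone marrow cultures, 4 arrays for each of 4 groups. Progenitors were c-kit-positive cells separated magnetically on day 6 of culture. BMMC are bone marrow-derived mast cells grown for 4 weeks in IL-3 at 5 ng/ml and SCF at 20 ng/ml. MMC are mast cells driven to a mucosal type by 5 days with IL-9 and TGF-beta. IgE_BMMC are mast cells loaded with an anti-DNP IgE and then exposed to DNP antigen for 2 hours. Per the labels, 100 ng of total RNA with an integrity number above 8 was labelled for each array. The series describes the 4 arrays of a group as biological replicates; whether these were separate animals or separate cultures is not given in the sources used here, so the p values measure the spread between these samples, which may be technical in part.

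Per the file headers, the authors extracted spot signals with Agilent Feature Extraction 9.5.1.1, and the deposited spot signals are intensity values on a linear scale after subtraction of a spatially detrended background, with no scaling between arrays. The authors also gave a value table in log2 units with 599 entries, of which 22 are controls. It could be rebuilt from the deposited per-miRNA total signal: that signal, raised to at least 1, was put on the log2 scale, the 75th percentile of all entries was subtracted on each array, and each entry was centred on its median over the 16 arrays. The largest difference between the rebuilt and the given values was 0.016 log2. The array medians in that table ran from -0.98 to 0.82, so it was used as an alternative and not as the source of the main values.

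Each array holds 12493 spots, of which 11540 report on 1712 probes for 577 miRNAs and 953 are controls. The mouse contributes 567 of the miRNAs and viruses contribute 10. A miRNA has 1 probe in 3 cases, 2 in 287, 3 in 13 and 4 in 274. No spot was saturated, and on average 21.6% of the probes were well above background by the extraction software's own call. The spots of a probe were averaged without control spots and without spots that the software marked as outliers. Each array was divided by a scale factor, the 75th percentile of the 205 probes that were well above background on all 16 arrays, set to a geometric mean of 1 over the arrays. Values were raised to a floor of 11.8 and put on the log2 scale, and the brightest probe stood for its miRNA.

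A miRNA was fitted when it was well above background on at least 3 arrays of a group, which left 217, of which 7 sat at the floor on all 16 arrays. In each comparison it was tested when at least 1 of the 2 groups met that condition. The model in limma 3.58.1 had 1 coefficient per group and all 16 arrays, with empirical Bayes moderation (12 residual and 0.876 prior degrees of freedom). P values were adjusted by the Benjamini-Hochberg method within a comparison, and a miRNA was called at an adjusted p under 0.05. Values are log2 differences with the model's standard error (SE), from 4 arrays per group. Where a miRNA was well above background on no array of 1 group, its fold is a lower bound: the mean of the bright group was set against the higher, array by array, of the lowest signal among the probes well above background and the dim probe's own signal. The numbers of miRNAs well above background per array were compared by exact two-sided permutation tests over the 70 arrangements of 4 against 4 arrays, which can give no p under 0.0286, with Benjamini-Hochberg adjustment over the 4 comparisons.

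Before the data were examined, 22 lists of miRNAs, the tests, the rule for naming miRNAs and most alternatives were fixed. The lists are the miR-132 and miR-212 cluster, the miR-221 and miR-222 cluster, inflammatory response miRNAs, the miR-17-92 and paralogous clusters, the let-7 family, myeloid, haematopoietic progenitor, erythroid and megakaryocytic, lymphoid and stromal miRNAs, the miR-15/16, miR-29, miR-30 and miR-200 families, the miR-23/27/24 clusters, the miR-34 family with miR-210, the Dlk1-Dio3 imprinted cluster, the Sfmbt2 intronic cluster, muscle, liver and neuron miRNAs, tRNA and rRNA fragments named as miRNAs, viral miRNAs, and star arms, the passenger strands of hairpins. Lists with at least 3 tested members were tested with camera in limma at a preset correlation of 0.01, beside an estimated correlation and fry. The lists share members: 8 on the myeloid list, 6 on the miR-23/27/24 list, 5 on the inflammatory list and 72 among the star arms also stand on another list.

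The rule names, in each comparison, the 10 largest rises and 10 largest falls among called miRNAs whose groups do not overlap, 10 fixed miRNAs (miR-132, miR-212, miR-155, miR-221, miR-222, miR-146a, miR-21, miR-223, miR-126-3p and miR-9), and up to 4 tested members with the lowest adjusted p from each list, of which the text names only part. MiR-9 was well above background on no array and was tested in no comparison. MiR-126-3p was tested only against the progenitors. Names outside the rule are given as chosen after their values were seen.

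Coordinates are those of the brightest probe of a miRNA in the array annotation, on the mm9 build. Host genes come from the gene names table of the reference, which is on another build. Of the 567 mouse miRNAs, 490 matched a symbol, 559 have coordinates and 337 lie within a gene. No exon or intron was assigned.

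The alternatives were 4 other scalings between arrays (the 75th percentile of all miRNA probes, the median of the probes detected on all arrays, quantile normalisation and no scaling), normexp background correction with an offset of 50, the authors' value table, the per-miRNA total signal, the mean of all probes, other filters, a floor 4 times higher or lower, replicate number or slide as a block, only the 2 groups compared, trended and robust moderation, a further limit of 2-fold, and leaving out each array in turn. The 16 arrays sit on 2 slides, each with 2 arrays of every group, and each replicate number occurs once per group, so neither a slide nor a replicate block can move a difference between groups, only its SE and the calls. The 2 scan times coincide with the slides, so a scan block was not run apart from the slide block. No scaling leaves the brightness of whole arrays in the values, and the normexp offset lifts dim probes on dim arrays, both by construction. Fits within a slide and a filter on values above the floor on at least 1 array were chosen after seeing the data.

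The fit and the list test were run on simulated data of 217 miRNAs in 20 runs. Changes were put into the MMC arrays alone and tested against BMMC. The fit called 66.8% of changes of 0.5 log2, 90.0% of changes of 1 and 93.7% of changes of 2, and 1.73% of unchanged miRNAs. Estimated changes were 0.955, 0.914 and 0.860 of the true ones. Simulated miRNAs started at least 0.5 log2 above the floor, which favours recovery. A raised list was called in 100% of runs and an unchanged list in 0%. The noise was independent between miRNAs, the arrays did not differ in brightness, and scaling and probe choice were not run. These rates thus do not cover errors from scaling or from correlation between miRNAs. Work was done in R 4.3.3 with the data.table package, version 1.17.8, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. Replicate numbers were not taken as pairs between groups. The deviations from the group means of arrays with the same number correlated at -0.41 to 0.46 over all comparisons, and in MMC against IgE_BMMC all 4 were positive, from 0.075 to 0.46, the lowest under the limit of 0.1 set for pairing.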

Results

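MicroRNA levels were measured in mouse bone marrow-derived mast cells at 4 stages: c-kit-positive progenitors, cultured mast cells (BMMC), mast cells of a mucosal type (MMC) and mast cells activated through IgE (IgE_BMMC). Each group has 4 arrays, and the 16 arrays sit on 2 slides with 2 arrays of every group on each. With 4 arrays per group, their number limits the precision. A test for a difference between slides with limma called 0 of 217 miRNAs, with 9 at an unadjusted p under 0.05.

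The BMMC arrays showed the most miRNAs, with 211 ± 10.05 (SD, n = 4) well above background, and the IgE_BMMC arrays the fewest, with 152.5 ± 6.24 (SD, n = 4). The progenitor arrays showed 165.5 ± 18.6 and the MMC arrays 179 ± 9.49 (SD, n = 4 each). The differences were 45.75 miRNAs for BMMC against progenitors, -32.25 for MMC against BMMC, -58.75 for IgE_BMMC against BMMC and 26.5 for MMC against IgE_BMMC, each with an adjusted p of 0.0286 in an exact two-sided permutation test, the smallest that 70 arrangements can give. Without BMMC replicate 2 the difference of MMC from BMMC was -28, with an adjusted p of 0.0571 in the exact permutation test. The BMMC arrays left (200 to 213 miRNAs) still all lay above the MMC arrays (171 to 192), with fewer arrangements to test them. The 75th percentile of the raw signal was 393 ± 52.6 intensity units in progenitors, 1578 ± 199 in BMMC, 780 ± 62.1 in MMC and 385 ± 50.2 in IgE_BMMC (SD, n = 4 each). The bright corner control features of the arrays read 1431 ± 160, 1283 ± 166, 773 ± 96.6 and 423 ± 137 in the same order.

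**Figure D1:**
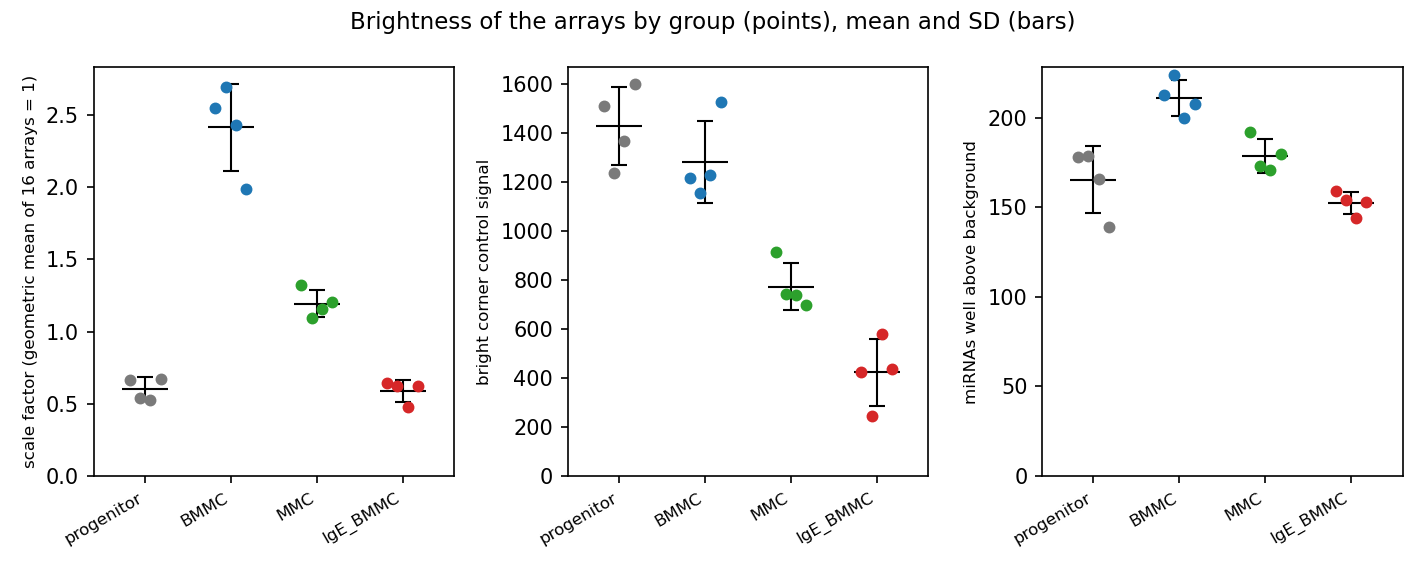
Scale factor (ratio), bright corner control signal (intensity units) and number of miRNAs well above background on each of the 16 arrays by group, with the mean and SD of 4 arrays. The scale factor averaged 2.42 in BMMC, 1.19 in MMC, 0.601 in progenitors and 0.590 in IgE_BMMC.

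Across 217 miRNAs, arrays of the same group correlated with a median r of 0.994 over 24 pairs (0.938 to 0.998), and arrays of different groups with a median r of 0.922 over 96 pairs (0.811 to 0.990). These correlations run across miRNAs, which are not independent replicates. The first principal component held 73.3% of the variance and placed the progenitors between -15.29 and -13.34 and all other arrays between 3.38 and 5.96. The second, with 10.6%, ordered MMC (-5.32 to -2.48), BMMC (-1.86 to 0.18) and IgE_BMMC (4.20 to 4.88). The third, with 7.26%, set progenitor replicate 4 apart from all other arrays (-8.84).

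BMMC were set against progenitors to ask how the miRNAs change while bone marrow progenitors mature into mast cells. The clusters related to miR-17-92, which favour proliferation, fell together: all 16 tested members were lower in BMMC, by a median log2 difference of -2.53. Within them miR-18a fell 10.1-fold (log2 -3.33, SE 0.16), miR-17 fell by 3.25 on the log2 scale (SE 0.19) and miR-92a fell 6.67-fold (-2.74, SE 0.12; n = 4 arrays per group throughout). MiR-223, a miRNA of granulocytes and monocytes, fell 17.3-fold, from 12.35 ± 0.34 to 8.23 ± 0.26 (log2, SD). MiR-451, a miRNA of red cell precursors, was well above background on 4 progenitor arrays and on 0 BMMC arrays. It was at least 41.0-fold lower under the main scaling and at least 10.2-fold without scaling. The fit, with values raised to the floor, put it at -3.72 log2. The p53-responsive miR-34a rose 7.31-fold (log2 2.87, SE 0.22), and miR-22, miR-146b, miR-29b and miR-29c rose between 2.35-fold and 2.87-fold.

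Of 217 miRNAs tested, 144 were called, 46 higher and 98 lower in BMMC, and 69 of them changed at least 2-fold. The arrays of the groups did not overlap for 56.2% of tested miRNAs, where chance gives 2.86% for each miRNA. The miRNAs share arrays, scale factors and a floor, so an error of scaling can move many of them together. The adjusted p was 5.83e-10 for miR-223, 1.17e-09 for miR-451, 5.68e-10 for miR-18a, 2.85e-09 for miR-17, 4.79e-10 for miR-92a and 5.57e-08 for miR-34a. Among the further large falls, miR-130a dropped 11.4-fold (adjusted p = 4.79e-10), miR-106a 8.99-fold, miR-711 8.71-fold, miR-146a 8.56-fold, miR-19a 8.50-fold and miR-20b 8.10-fold. The rises also held miR-135a* (6.58-fold), miR-34b-5p (5.63-fold), miR-874 (4.54-fold), miR-877 (4.37-fold) and miR-33 (2.54-fold, but -0.089 log2 under normexp correction). Within slide 1 and slide 2 the log2 differences were -4.33 and -3.60 for miR-223, -3.07 and -3.13 for miR-17, and 2.91 and 3.12 for miR-34a. A second detected probe pointed the other way for 4 of 132 called miRNAs with at least 2 detected probes: miR-34b-5p (-0.02), miR-874 (-0.38), and miR-452 and miR-762, named after their values were seen (main values 0.57 and 0.45). The call of miR-452 outlasted the removal of 1 array only for progenitor replicates 1 and 4 and BMMC replicate 1 (0.47 to 0.86), and that of miR-762 only for progenitor replicates 3 and 4, MMC replicates 1, 3 and 4 and IgE_BMMC replicates 1, 2 and 4 (0.33 to 0.64).

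The list of miR-17-92 and paralogous clusters had 0 members higher and 16 lower (also 0 and 16 adjusted over the list alone; range -3.33 to -0.65), although without scaling 11 were called lower and 2 higher. Its camera adjusted p was 2.28e-05, and adjusted p = 0.361 with an estimated correlation; the list's median was -2.70 on slide 1 and -2.28 on slide 2. In the miR-23/27/24 clusters 6 of 7 tested members rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.60 (0.58 on slide 1, 0.93 on slide 2), while normexp correction called 5 higher and 2 lower. Their camera adjusted p was 0.000407, and adjusted p = 0.218 with an estimated correlation. MiR-23b rose 2.22-fold, miR-27b 1.96-fold and miR-24 1.53-fold. In the miR-34 family with miR-210, 2 of 3 members rose, miR-34a and miR-34b-5p (2 adjusted over the list alone), and camera gave an adjusted p of 0.0706. The miR-29 family had 3 members higher and 1 lower (the same adjusted over the list alone; adjusted p = 0.0706), with a median of 0.48 (0.33 on slide 1, 0.96 on slide 2) that turned to -0.16 under normexp correction.

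The haematopoietic progenitor list had 0 members higher and 5 lower of 7 (0 and 6 adjusted over the list alone), with a median of -0.99 (-1.74 on slide 1, -0.20 on slide 2) that turned positive under the percentile of all probes (0.19) and without scaling (0.56). MiR-196b was at least 17.0-fold lower (4.22-fold without scaling) and miR-126-3p, a stem cell and endothelial miRNA, at least 9.83-fold lower (2.44-fold without scaling), each well above background on 0 BMMC arrays. With values raised to the floor, the fits without 1 array gave -2.71 to -2.23 and -1.92 to -1.59 log2. Among the lymphoid miRNAs 0 were higher and 4 lower of 7 (0 and 4 adjusted over the list alone). MiR-181d fell 4.77-fold and miR-181b 3.47-fold (0.21 log2 without scaling), but the list's median of -0.47 (-0.43 on slide 1, -0.15 on slide 2) was positive under 5 alternatives, among them quantile normalisation (0.40). Of 3 erythroid and megakaryocytic miRNAs, miR-451 fell (1 adjusted over the list alone), while miR-486 (-0.39) and miR-150 (-0.18), above background on 0 progenitor arrays, were not called. Both were called higher under the percentile of all probes (0.28 and 1.32), quantile normalisation (0.47 and 0.86) and without scaling (0.94 and 1.79). Beside the negative main values, this leaves their direction not settled. Normexp correction called them lower (-1.69 and -1.36), but by construction it lifts dim probes on dim arrays. The myeloid list had 5 members higher and 5 lower of 12 (5 and 5 adjusted over the list alone), miR-142-3p among the latter (2.12-fold; 0.93 log2 without scaling). The miR-221 and miR-222 cluster had both members lower (2 adjusted over the list alone; miR-221 1.40-fold, miR-222 1.93-fold), yet a median of 0.83 under the percentile of all probes and 1.29 without scaling. In the miR-132 and miR-212 cluster miR-212 fell 1.79-fold, though it was 0.71 log2 higher under the percentile of all probes. MiR-132 was called higher by limma (1 up and 1 down adjusted over the list alone), but it was well above background on 0 progenitor arrays. Its -1.27 under normexp correction is no evidence, since that correction by construction lifts dim probes on dim arrays. Its 0.46 log2 is the distance to the floor, so no rise is shown. Of the 46 higher calls, 6 had no lower bound above 0 in this way, among them miR-132, miR-152 and miR-762.

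In the inflammatory list 2 members rose and 2 fell of 6 (2 and 2 adjusted over the list alone): miR-155 fell 2.95-fold (log2 -1.89 on slide 1 and -0.95 on slide 2, -0.016 under the percentile of all probes and 0.44 without scaling), and miR-21 rose 1.18-fold (adjusted p = 0.0245), a call that ended without progenitor replicate 1 or 3 or BMMC replicate 2 or 4 (log2 0.17 to 0.53). The let-7 family had 3 members higher and 2 lower of 11 (1 and 1 adjusted over the list alone), with let-7i up 1.91-fold. The miR-15/16 family had 2 higher and 4 lower of 6 (2 and 4 adjusted over the list alone), miR-15b* down 2.57-fold (0.18 log2 under the percentile of all probes, 0.64 without scaling), and the miR-30 family 0 higher and 1 lower of 7 (0 and 1 adjusted over the list alone). Of 5 Dlk1-Dio3 miRNAs, miR-370 fell 3.27-fold (0.30 log2 without scaling) and miR-494 rose by 0.74 log2 (1 and 1 adjusted over the list alone), the latter no longer called without progenitor replicate 2 or 3 or BMMC replicate 2 (0.54 to 1.03). Both tested Sfmbt2 miRNAs fell (2 adjusted over the list alone), miR-467b at least 8.37-fold (2.08-fold without scaling) and miR-466f-3p 3.11-fold, to the floor on 3 BMMC arrays. The bound of miR-467b does not use that floor, with which the fits without 1 array gave -1.52 to -1.35 log2. The tRNA and rRNA fragments miR-805 and miR-720 fell 4.79-fold and 2.35-fold (2 adjusted over the list alone), with a list median of 0.26 without scaling. Among 32 star arms 4 were higher and 15 lower (4 and 15 adjusted over the list alone), miR-17* down 5.11-fold, and their median of -0.44 (-0.34 on slide 1, -0.17 on slide 2) was positive under 4 alternatives (0.67 without scaling). Of 2 stromal miRNAs miR-152 was called higher by limma (1 adjusted over the list alone). It was above background on 0 progenitor arrays and had no lower bound above 0, so no rise is shown for it either. Normexp correction, with the limit given for miR-132, put it at -1.35. Neither miR-200 member and not the 1 tested miRNA of muscle, liver and neurons, miR-219 (-0.17; 0.69 under the percentile of all probes, 1.55 without scaling), was called. The viral mghv-miR-M1-2, kept as a background check, fell 1.76-fold and was 0.40 higher without scaling. Viral miRNAs were listed as absent from the cultures, so with this call the check was not passed. The same miRNA was also called in IgE_BMMC against BMMC and in MMC against IgE_BMMC. Camera adjusted p for the remaining lists ran from 0.535 to 0.804. The list's median and its test differ in sign for the inflammatory, let-7 and miR-30 lists, and its median and mean for the myeloid and Dlk1-Dio3 lists.

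The share of higher calls depends on the scaling and on 1 array: without progenitor replicate 4 the median of all tested miRNAs was 0 and 62 of 151 calls (41.1%) were higher. The median of all tested miRNAs was -0.30 in the main model, 0.72 under the percentile of all probes, 0.27 under quantile normalisation, 1.38 without scaling and -1.34 under normexp correction, and higher calls made up 31.9%, 79.4%, 64.2%, 85.9% and 12.5% of the calls. The direction of miR-223, miR-451, miR-17 and miR-34a was the same under every alternative run, but the sizes moved. The progenitor scale factors lay at -2.01 log2 against BMMC. Without scaling, any rise and any fall beyond that size must thus keep its sign above the floor. The percentile of all probes also moves these differences up together, so neither setting tests a single miRNA. Under the percentile of all probes and without scaling the values were -2.56 and -2.10 for miR-223, -1.79 and -1.33 for miR-18a, -1.70 and -1.24 for miR-17, -1.19 and -0.73 for miR-92a, and 4.42 and 4.88 for miR-34a, which was 1.66 under normexp correction.

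**Figure D2:**
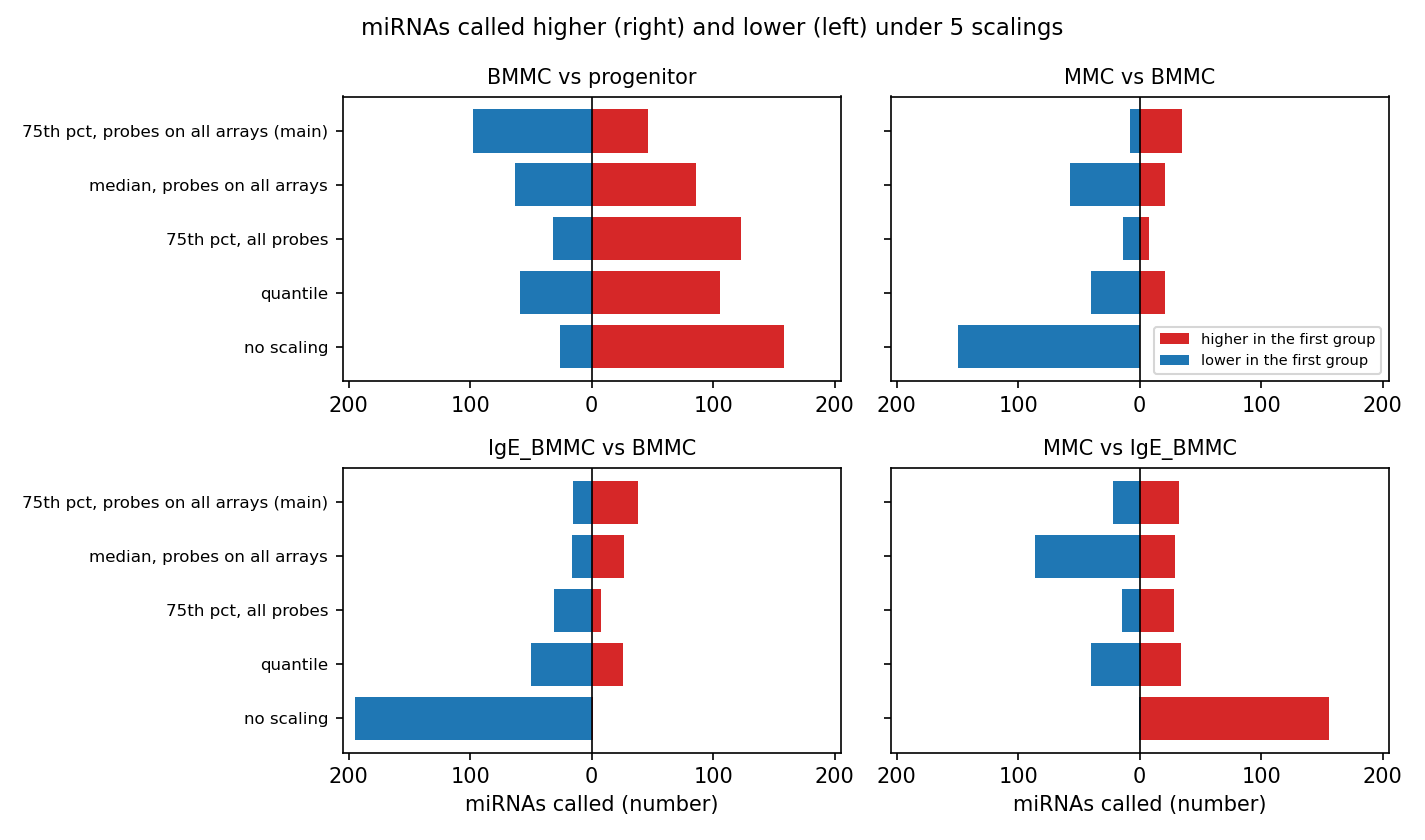
Number of miRNAs called higher (red, to the right) and lower (blue, to the left) in the 4 comparisons under 5 scalings between arrays. Without scaling, IgE_BMMC against BMMC gave 196 calls of which 0.51% were higher, where the main scaling gave 53 calls of which 71.7% were higher.

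MMC were set against BMMC to ask what IL-9 and TGF-beta change on the way to a mucosal type. No group is described as kept for those days without these cytokines, so their effect cannot be told apart from that of the culture. MiR-21, a TGF-beta-responsive and growth-promoting miRNA, rose 2.16-fold in MMC (log2 1.11, SE 0.09, n = 4 arrays per group), and miR-452 rose 2.29-fold (1.20, SE 0.24). MiR-193b and its cluster neighbour miR-365 fell 2.70-fold (-1.43, SE 0.23) and 1.82-fold (-0.86, SE 0.14), and miR-223 fell 1.80-fold (-0.85, SE 0.20). The miR-23/27/24 clusters, made in part with myeloid maturation, had 4 of 7 tested members higher and 0 lower. MiR-132, the miRNA for which the series is known, was not called here (-0.24).

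Of 207 miRNAs tested, 43 were called, 35 higher and 8 lower in MMC (38 and 26 without progenitor replicate 4, or 59.4% higher), and 5 changed at least 2-fold: miR-452, miR-21, miR-710 and miR-1224 upward and miR-193b downward. The groups did not overlap for 34.8% of tested miRNAs, against 2.86% by chance for each miRNA, which again share arrays and scale factors. The adjusted p was 2.11e-06 for miR-21, 0.00274 for miR-452, 0.000594 for miR-193b, 0.000627 for miR-365 and 0.00681 for miR-223. MiR-710 and miR-1224 rose 2.10-fold each, miR-370 1.99-fold, miR-24-2* 1.77-fold, miR-762 1.75-fold, and miR-125a-3p, miR-671-5p and miR-718 between 1.73-fold and 1.74-fold. The remaining falls were miR-212 (1.41-fold), miR-93 (1.38-fold), miR-128 (1.36-fold), miR-425 (1.20-fold) and miR-16 (1.16-fold). MiR-21 rose by 1.05 on slide 1 and 1.06 on slide 2, and miR-193b differed by -1.80 and -1.17.

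The miR-23/27/24 clusters had a median of 0.32 (0.35 on slide 1, 0.18 on slide 2), with 4 members higher (6 adjusted over the list alone), but -0.05 under the percentile of all probes and -0.69 without scaling. Their camera adjusted p was 0.011, and adjusted p = 0.523 with an estimated correlation. MiR-24-1* rose 1.68-fold, miR-23b 1.29-fold and miR-24 1.25-fold. The myeloid list, which shares miR-24 and others with these clusters, had 4 members higher and 1 lower of 12 (5 and 1 adjusted over the list alone), miR-142-3p up 1.44-fold and miR-223 down, but miR-142-3p was called lower under quantile normalisation (-0.26) and without scaling (-0.49). Of 5 Dlk1-Dio3 miRNAs 2 were higher (3 adjusted over the list alone), miR-370 and miR-770-3p (1.62-fold), with a list median of 0.64 that was -0.31 without scaling. In the inflammatory list only miR-21 was called of 6 members (1 higher and 1 lower adjusted over the list alone), with miR-146a at -0.45 and miR-155 at 0.40. Of the miR-17-92 clusters 1 was higher and 1 lower of 14 (1 and 1 adjusted over the list alone), miR-17* (1.42-fold) and miR-93, with a camera adjusted p of 0.052. In the miR-132 and miR-212 cluster miR-212 fell (1 adjusted over the list alone), although under normexp correction the list's median was 0.27.

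The miR-29 family had 1 member higher of 6 (1 adjusted over the list alone), miR-29a* (1.52-fold), the haematopoietic progenitor list 1 higher of 5 (1 adjusted over the list alone), miR-125a-3p, and the miR-15/16 family 1 lower of 6 (1 adjusted over the list alone), miR-16. The lymphoid list had 1 lower of 7 (0 adjusted over the list alone), miR-128, which normexp correction put at 0.52. Star arms had 6 higher and 0 lower of 29 (6 adjusted over the list alone). The erythroid and megakaryocytic list had 0 of 2 called (1 higher and 1 lower adjusted over the list alone; miR-150 -0.79) and the miR-221 and miR-222 cluster 0 of 2 (1 higher adjusted over the list alone; miR-221 0.27, miR-222 0.07). MiR-150 was called without progenitor replicate 2 or 4 or IgE_BMMC replicate 2 or 3 (-0.98 to -0.61 over all 16 removals), and miR-221 without progenitor replicate 2 or BMMC replicate 4 (0.16 to 0.37). The let-7, miR-30, miR-200, stromal, Sfmbt2, muscle, liver and neuron, tRNA and rRNA fragment and viral lists and the miR-34 family with miR-210 had 0 members called by limma, also 0 adjusted over the list alone. Camera adjusted p for the lists not called ran from 0.052 to 0.936. The list's median and its test differ in sign for the haematopoietic progenitor list and the miR-34 family, and its median and mean for the miR-29 family.

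Rises here depend on the scaling. Those of miR-452, miR-21, miR-710 and miR-1224 kept their sign under every scaling run (0.19, 0.10, 0.06 and 0.06 without scaling). The other named rises were negative without it. The scale factors differ by -1.01 log2, so above the floor only a larger rise can stay positive without scaling. That setting thus tests no single miRNA. The median of all tested miRNAs was 0.01 in the main model, -0.22 under the percentile of all probes, -0.10 under quantile normalisation and -0.86 without scaling, and higher calls made up 81.4%, 36.4%, 34.4% and 0% of the calls. Leaving out 1 array ended the call of miR-212 for BMMC replicates 3 and 4 and MMC replicates 1 and 3 (-0.61 to -0.38), of miR-425 for BMMC replicates 1, 3 and 4 and MMC replicates 1 and 4 (-0.37 to -0.22), of miR-17* for BMMC replicates 1 and 2 and MMC replicates 2 and 4 (0.39 to 0.61), and of miR-128 for every array but progenitor replicates 1, 2 and 4 and BMMC replicate 2 (-0.56 to -0.41).

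IgE_BMMC were set against BMMC to ask which miRNAs respond within 2 hours of IgE crosslinking. No group is described as loaded with IgE without antigen, so loading and handling cannot be told apart from the antigen. MiR-132, an activity-induced miRNA made from a CREB target transcript, rose 9.22-fold, from 4.01 ± 0.32 to 7.22 ± 0.12 (log2, SD, n = 4), and its cluster partner miR-212 rose 1.48-fold (log2 0.56, SE 0.15). MiR-21 rose 2.02-fold (1.01, SE 0.09), and both passenger arms of the miR-24 hairpins, miR-24-1* and miR-24-2*, rose 2.44-fold (1.28, SE 0.10) and 2.37-fold (1.24, SE 0.18). All 7 tested members of the miR-23/27/24 clusters were higher, by a median of 0.49. Without scaling between arrays every one was called lower, but so were 195 of the 196 miRNAs called there. MiR-494 and miR-135a* fell 2.31-fold (-1.21, SE 0.25) and 2.26-fold (-1.18, SE 0.18). MiR-21, miR-24-1* and miR-24-2* were also higher in MMC against BMMC, by 1.11, 0.75 and 0.82 log2, while miR-132 and miR-212 were not. Rises shared with MMC cannot be credited to IgE alone, and the arrays of both groups were dimmer than those of BMMC.

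Of 207 miRNAs tested, 53 were called, 38 higher and 15 lower, and 7 changed at least 2-fold: miR-132, miR-24-1*, miR-24-2*, miR-21* and miR-21 upward and miR-494 and miR-135a* downward. The count was 33 without BMMC replicate 2 and 34 without IgE_BMMC replicate 2. The groups did not overlap for 28.5% of tested miRNAs, against 2.86% by chance for each miRNA, which again share arrays and scale factors. The adjusted p was 1.03e-09 for miR-132, 0.0144 for miR-212, 2.11e-06 for miR-21, 6.3e-07 for miR-24-1*, 0.000259 for miR-24-2*, 0.00282 for miR-494 and 0.000369 for miR-135a*. The value of miR-21* (1.06 log2; -0.26 without scaling) is set by the floor, where all 4 BMMC values lay. MiR-29a*, miR-326, miR-17*, miR-22 and miR-340-3p rose between 1.64-fold and 1.66-fold. MiR-290-5p fell 1.87-fold and miR-874 fell 1.82-fold; miR-452, miR-125a-3p, miR-292-5p, miR-721, miR-680 and miR-139-3p had log2 differences between -0.81 and -0.65. Under normexp correction, which by construction lifts dim probes on dim arrays, miR-290-5p (0.24), miR-452 (0.98), miR-125a-3p (0.66) and miR-292-5p (0.95) were called higher instead. A second detected probe pointed the other way for 1 of 51 called miRNAs, miR-374 (0.28 against -0.06), named after its values were seen.

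The rise of miR-132 (log2 3.20) was 3.01 on slide 1 and 3.34 on slide 2, 3.18 by its other probe, and 1.17 without scaling. Both members of its cluster were higher (2 adjusted over the list alone), which is not independent evidence for miR-132, since the series is known for it, and miR-212 was -1.47 without scaling. The second probe of miR-212 gave 1.69. The miR-23/27/24 clusters had 7 members higher and 0 lower (7 adjusted over the list alone; median 0.50 on slide 1, 0.43 on slide 2, -1.54 without scaling), among them miR-23b (0.51) and miR-24 (1.40-fold). Their camera adjusted p was 2.29e-05, and adjusted p = 0.0797 with an estimated correlation. The myeloid list had 7 higher and 0 lower of 12 (8 and 1 adjusted over the list alone), with a median of 0.33 (0.49 on slide 1, 0.22 on slide 2, -1.55 without scaling). It includes miR-142-3p (1.52-fold, but called lower under quantile normalisation, -0.26), and miR-223 (0.27) was not called. Its camera adjusted p was 0.00298, and adjusted p = 0.173 with an estimated correlation. The inflammatory list had 3 higher and 0 lower of 6 (3 adjusted over the list alone), miR-21, miR-21* and miR-146b (0.24), with a median of 0.35 (0.59 on slide 1, 0.10 on slide 2, -1.29 without scaling). Its camera adjusted p was 0.023, and adjusted p = 0.173 with an estimated correlation, and neither miR-155 (0.30) nor miR-146a (0.39) was called. The Dlk1-Dio3 list had 0 higher and 1 lower of 5 (0 and 2 adjusted over the list alone), miR-494, with a median of -0.41 (-0.50 on slide 1, -0.38 on slide 2) that was 1.13 under normexp correction. Its camera adjusted p was 0.0394, and adjusted p = 0.157 with an estimated correlation.

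Both members of the miR-221 and miR-222 cluster, which targets the c-kit receptor, were called higher (2 adjusted over the list alone; miR-221 0.34, miR-222 0.45), with a median of -1.64 without scaling. Leaving out BMMC replicate 1, 2 or 3 or any IgE_BMMC array ended the call of miR-221 (0.25 to 0.43), and leaving out any array but progenitor replicates 1, 2 and 3 and BMMC replicate 1 ended that of miR-222 (0.34 to 0.57). The miR-30 family had 2 higher of 7 (3 adjusted over the list alone), miR-30c (0.43) and miR-30d (0.32), both negative without scaling. The miR-17-92 clusters had 2 higher of 14 (1 adjusted over the list alone), the miR-29 family 1 of 6 (1 adjusted over the list alone), and star arms 7 higher and 1 lower of 29 (8 and 1 adjusted over the list alone). The haematopoietic progenitor list had 1 lower of 5, miR-125a-3p, and the stromal list 1 lower of 2, miR-152 (0 IgE_BMMC arrays above background, at least 1.15-fold), each also 1 adjusted over the list alone, and both turned positive under normexp correction (0.66 and 1.26). The tRNA and rRNA fragments miR-720 (0.41) and miR-805 (0.64) were called higher (2 adjusted over the list alone), with a list median of -1.51 without scaling. So was mghv-miR-M1-2, at 0.70 above the floor, where all 4 BMMC values lay (1 adjusted over the list alone, -0.55 without scaling). This viral miRNA was listed as absent from the cultures, so rises of this size or less call for caution. The let-7, lymphoid, erythroid and megakaryocytic, miR-15/16, miR-200, Sfmbt2 and muscle, liver and neuron lists and the miR-34 family with miR-210 had 0 members called by limma, also 0 adjusted over the list alone. Camera adjusted p for the lists not called ran from 0.244 to 0.945, and the median and the test differ in sign for the let-7 and miR-15/16 families.

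Without scaling every named rise except that of miR-132 turned negative. The scale factors differ by -2.03 log2, so above the floor any smaller rise must turn and any fall stay. This tests no single miRNA. The falls of miR-494, miR-135a*, miR-874, miR-721, miR-680 and miR-139-3p kept their sign under every scaling and under normexp correction. That correction left miR-721 at -0.08, miR-680 at -0.03 and miR-139-3p at -0.15, not called. The median of all tested miRNAs was 0.01 in the main model, -0.12 under the percentile of all probes, -0.09 under quantile normalisation and -1.83 without scaling, and higher calls made up 71.7%, 20.5%, 34.2% and 0.51% of the calls. Leaving out 1 array ended the calls of miR-452 (-0.90 to -0.73) and miR-146b (0.20 to 0.31) for BMMC replicate 2 and IgE_BMMC replicates 1, 2 and 4, of miR-326 for replicates 2 and 3 of both groups (0.58 to 0.82), and of miR-340-3p (0.64 to 0.81) and miR-720 (0.33 to 0.51) for BMMC replicates 1, 2 and 3 and IgE_BMMC replicates 1, 2 and 4. It ended that of miR-152 for BMMC replicates 1 and 3 and IgE_BMMC replicates 1, 3 and 4 (-0.55 to -0.28), that of miR-805 for every array but the progenitors and BMMC replicate 4 (0.54 to 0.75), and that of miR-292-5p for every array but progenitor replicates 1, 2 and 4 (-0.84 to -0.69).

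**Figure D3:**
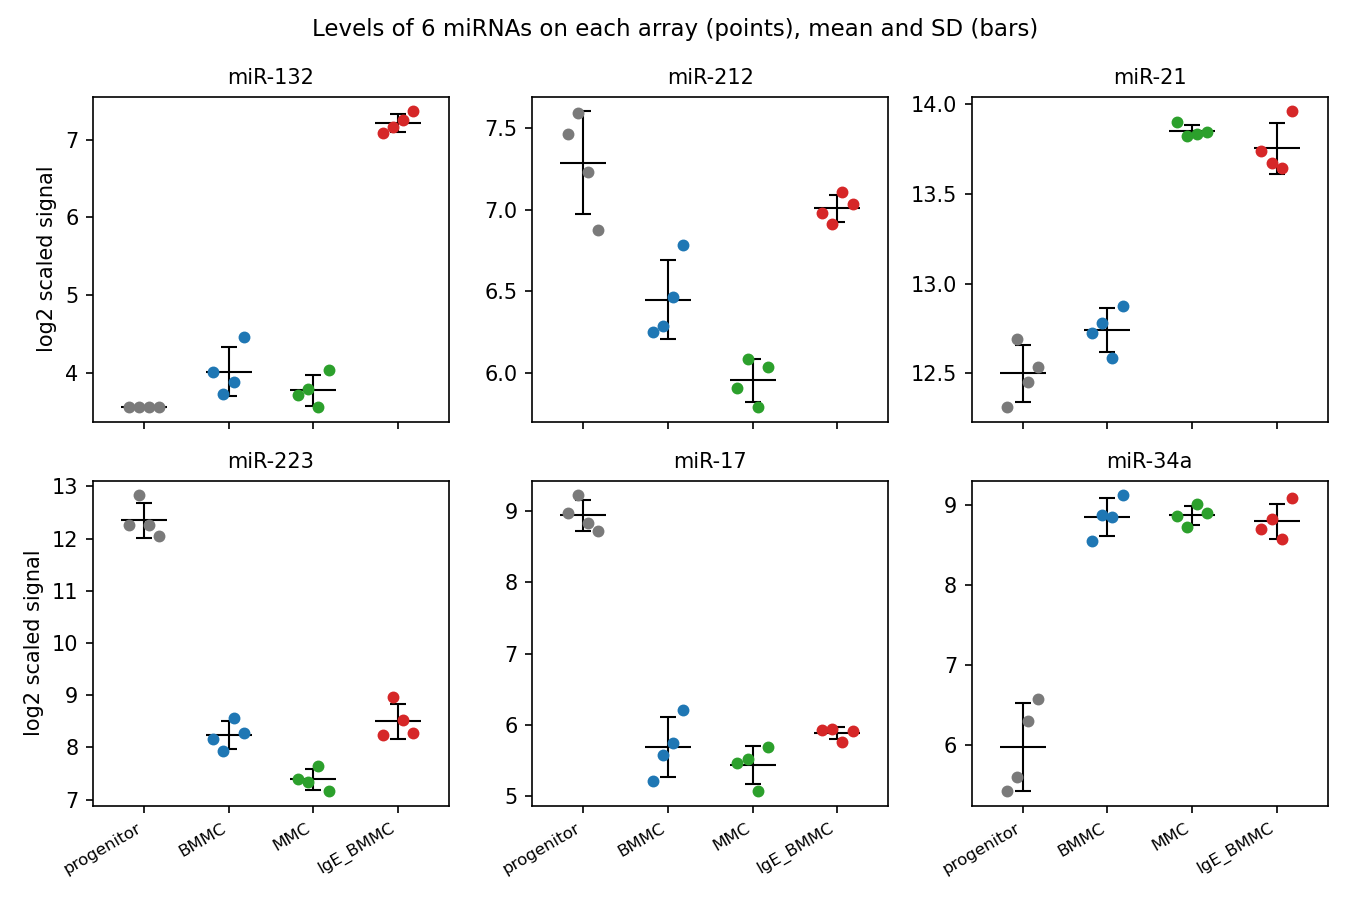
Log2 scaled signal of miR-132, miR-212, miR-21, miR-223, miR-17 and miR-34a on each array by group, with the mean and SD of 4 arrays. MiR-132 averages 7.22 in IgE_BMMC and 4.01 in BMMC. Without scaling between arrays, which leaves their brightness in the values, the rises of miR-21 and miR-212 after IgE turn negative.

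MMC were set against IgE_BMMC as a direct test of whether mucosal differentiation and IgE activation differ, since both were compared with the same BMMC arrays. MiR-132 was 10.9-fold lower in MMC than after IgE crosslinking (log2 -3.44, SE 0.13, n = 4 arrays per group), and miR-212 was 2.08-fold lower (-1.05, SE 0.15). MiR-193b and miR-365 were 2.84-fold (-1.51, SE 0.23) and 2.002-fold lower (SE 0.14 on the log2 scale; miR-365 0.02 without scaling), and miR-223 was 2.17-fold lower (-1.12, SE 0.20). MiR-452 was 4.02-fold higher in MMC (2.01, SE 0.24), miR-135a* 3.30-fold (1.72, SE 0.18) and miR-494 3.15-fold (1.66, SE 0.25). MiR-21, called higher in both groups against BMMC, differed by 0.10 and was not called.

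Of 174 miRNAs tested, 54 were called, 32 higher and 22 lower in MMC, and 27 changed at least 2-fold. Without progenitor replicate 4 the count was 95, of which 34.7% were higher. The groups did not overlap for 43.7% of tested miRNAs, against 2.86% by chance for each miRNA, which again share arrays and scale factors. The adjusted p was 3.51e-10 for miR-132, 7.88e-05 for miR-212, 0.000159 for miR-193b and for miR-494, 0.000534 for miR-223, 2.69e-05 for miR-452 and 9.77e-06 for miR-135a*. The other large rises were miR-125a-3p (2.96-fold), miR-292-5p (2.80-fold), miR-370 (2.75-fold), miR-680 (2.69-fold), miR-877 (2.66-fold), miR-762 (2.64-fold) and miR-290-5p (2.62-fold), of which miR-292-5p (-0.13), miR-370 (-0.13) and miR-762 (-0.28) turned negative under normexp correction. MiR-21* (-0.98) and miR-146a (-0.85; 0.02 without scaling) were lower, with values at the floor on 3 MMC arrays each, and so were miR-326 (1.68-fold; 0.28 log2 without scaling) and miR-24-1* (1.45-fold; 0.49 without scaling). MiR-132 differed by -3.46 on slide 1 and -3.48 on slide 2 and miR-452 by 1.94 and 2.03. Leaving out 1 array ended the call of miR-146a for all but the progenitors, BMMC replicate 1 and IgE_BMMC replicates 1 and 4 (-1.04 to -0.77), and that of miR-93 for all but progenitor replicates 2, 3 and 4, BMMC replicates 1 and 4 and MMC replicate 4 (-0.47 to -0.32).

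Both members of the miR-132 and miR-212 cluster were lower (2 adjusted over the list alone; median -2.25). All 4 tested members of the Dlk1-Dio3 cluster were higher (4 adjusted over the list alone), with a median of 1.27 (1.28 on slide 1, 1.29 on slide 2) that was -0.23 under normexp correction: miR-494, miR-370, miR-770-3p (0 IgE_BMMC arrays above background, at least 1.79-fold) and miR-134 (2.07-fold). Their camera adjusted p was 0.00558, and adjusted p = 0.168 with an estimated correlation. The inflammatory list had 0 higher and 3 lower of 5 (0 and 3 adjusted over the list alone; median -0.43, 0.59 without scaling), miR-21*, miR-146a and miR-146b (1.35-fold), and miR-155 (0.09) was not called. The myeloid list had 0 higher and 4 lower of 10 (0 and 4 adjusted over the list alone; median -0.18, 0.85 without scaling) and the miR-23/27/24 clusters 0 higher and 3 lower of 7 (0 and 3 adjusted over the list alone; median -0.17, 0.85 without scaling), each with a camera adjusted p of 0.108.

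The let-7 family had 1 lower of 11 (1 adjusted over the list alone), let-7c (-0.33), and the miR-17-92 clusters 1 lower of 13 (0 adjusted over the list alone), miR-93 (-0.36), both higher without scaling (0.69 and 0.66). The miR-15/16 family had 1 lower of 6 (0 adjusted over the list alone), the haematopoietic progenitor list 1 higher of 4 (1 adjusted over the list alone), miR-125a-3p, and star arms 1 higher and 4 lower of 18 (1 and 3 adjusted over the list alone). Of the tRNA and rRNA fragments miR-720 (-0.48) was called of 2 (2 lower adjusted over the list alone), and mghv-miR-M1-2 was 1.48-fold lower (1 adjusted over the list alone), both higher without scaling (0.54 and 0.44). The miR-221 and miR-222 cluster (miR-221 -0.07, miR-222 -0.38), the lymphoid, erythroid and megakaryocytic, stromal, miR-29, miR-30 and Sfmbt2 lists and the miR-34 family with miR-210 had 0 members called by limma, also 0 adjusted over the list alone. MiR-221 was called without progenitor replicate 4 (-0.18), and miR-222 without progenitor replicate 2 or 4 or BMMC replicate 1 (-0.49 to -0.30 over all 16 removals). The miR-200 and muscle, liver and neuron lists had no tested member. Camera adjusted p for the lists not called ran from 0.108 to 0.968, and the lymphoid list's median and test differ in sign.

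Under every scaling and normexp correction, miR-452, miR-135a*, miR-494, miR-125a-3p, miR-290-5p, miR-680 and miR-877 were higher and miR-132, miR-193b, miR-223, miR-21* and miR-212 lower in MMC. Of these only miR-132 was called lower without scaling (-2.42), with miR-193b at -0.48, miR-223 at -0.09 and miR-21* and miR-212 at -0.03 each, and normexp correction left miR-452 at 0.08 and miR-125a-3p at 0.16, not called. The scale factor averaged 1.19 in MMC and 0.590 in IgE_BMMC, so above the floor any rise must stay positive without scaling. That setting thus tests none of these rises. The median of all tested miRNAs was -0.07 in the main model, -0.21 under the percentile of all probes, -0.16 under quantile normalisation, -0.32 under the median of the detected probes and 0.94 without scaling, and higher calls made up 59.3%, 65.1%, 45.9%, 25.2% and 99.4% of the calls.

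The coordinates here are those of the brightest probe of a miRNA on the mm9 build and may not span the whole miRNA. Host genes come from a table on another build. The miR-132 probe lies on chromosome 11 from 74987231 to 74987246 and the miR-212 probe beside it from 74986953 to 74986966. The miR-21 probe lies on chromosome 11 from 86397622 to 86397641, with the miRNA within Vmp1. The miR-223 probe lies on chromosome X from 93438224 to 93438244, with the miRNA within F630028O10Rik. The miR-17 probe lies on chromosome 14 from 115442915 to 115442928, and the miR-34a probe on chromosome 4 from 149442584 to 149442603. The miR-451 probe lies on chromosome 11 from 77886688 to 77886709, and the miR-193b probe on chromosome 16 from 13449668 to 13449684. The miR-452 probe lies on chromosome X from 69507610 to 69507626, with the miRNA within Gabre, and the miR-494 probe on chromosome 12 from 110953585 to 110953598.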

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

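The tests of the dim arrays were chosen only after the results were seen, and so was the screening of negative controls, other control features and further signal measures of whole arrays. Groups of 4 arrays were screened for an array far from the other 3, by the gap to its nearest neighbour over the whole range, against Dixon's critical value for 4 samples. Of 326 groups of 4 values screened, 27 passed (8.28%), where chance gives about 5%, and 9 of these lie in IgE_BMMC replicate 3 and 5 in progenitor replicate 4. Several measure the same thing on 1 array and are not independent.

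The scale factor of IgE_BMMC replicate 3 was 0.476, with the other 3 between 0.619 and 0.642, and so stood its 75th percentile of the raw signal (311 intensity units, others 405 to 419), summed signal over all miRNAs (47322, others 64472 to 67047) and control features hur_2 (4189, others 7335 to 7871) and hur_6 (1019, others 1650 to 1767). The lowest raw signal well above background was 39.2 intensity units on progenitor replicate 4 and 8.65 to 10.7 on the others, or 58.3 and 16.05 to 20.2 after scaling. Negative control spots there had a mean of 3.35 (others 0.878 to 1.25) and an SD of 5.59 (others 2.40 to 2.67). On IgE_BMMC replicate 2 their mean was 27.5 (others 0.546 to 1.27) and their SD 695 (others 1.93 to 6.00). This came from 1 of 672 spots, at 18011 and marked as an outlier by the software, without which the mean was 0.738 and the SD 2.31. The SD of the negative controls also stood apart on BMMC replicate 3 (5.86, others 1.96 to 2.37) and MMC replicate 4 (3.53, others 2.05 to 2.30). On the log2 scale, IgE_BMMC replicate 3 also stood apart for miR-155 (5.92, others 6.23 to 6.29), miR-17 (5.76, others 5.92 to 5.95), miR-29a (9.94, others 9.69 to 9.72) and miR-29a* (5.87, others 5.53 to 5.55). BMMC replicate 2 stood apart for miR-125a-3p (5.94, others 5.40 to 5.47), miR-680 (7.51, others 7.10 to 7.17) and miR-762 (4.53, others 4.17 to 4.22). Progenitor replicate 2 did so for miR-146a (7.92, others 6.88 to 7.05), miR-15b* (6.39, others 6.16 to 6.18) and miR-221 (9.61, others 9.23 to 9.28), and progenitor replicate 4 for miR-27b (9.63, others 9.48 to 9.49). The remaining values were miR-155 on BMMC replicate 1 (6.14, others 5.74 to 5.80), miR-30c on MMC replicate 3 (8.33, others 8.12 to 8.15) and miR-365 on IgE_BMMC replicate 4 (7.04, others 7.46 to 7.50).

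Control features that no comparison used also gave signal. The features named hur_1, hur_2, hur_4, hur_6 and mr_1, whose targets are not given in the sources used here, had array means of 2204 to 13160, 4189 to 42181, 1028 to 6210, 1019 to 7490 and 163 to 1359 intensity units.

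The progenitor, MMC and IgE_BMMC arrays were dimmer than the BMMC arrays. For MMC and IgE_BMMC, a lower yield of whole arrays in hybridisation or scanning is a candidate explanation: the bright corner features, relative to BMMC, were at -0.73 log2 (SE 0.12) in MMC and -1.66 (SE 0.27) in IgE_BMMC, beside scale factors at -1.01 and -2.03, and the median of the 5 other control features was -1.32 and -1.98. As the whole cause there, less labelled miRNA would leave level any controls that do not depend on the labelled sample. Whether the corner features are such controls was not tested. If they are, their fall argues against this cause, since the scale factor differed from them by only -0.28 (SE 0.17) and -0.38 (SE 0.31). For the progenitors the corner features were at 0.16 (SE 0.12) against a scale factor at -2.01, a gap of -2.17 (SE 0.18). If they are such controls, this argues against a lower yield as the whole cause. The median of the 5 other control features was 0.15, but hur_1 was at -0.58 (SE 0.11) and hur_4 at -0.73 (SE 0.15), so a lower yield may still have had a part. Less labelled miRNA is consistent with that gap, and whether the cells held less miRNA, as a difference between cell stages, or their RNA was labelled less well stays open, as the design gives no test of it.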

How the results depend on the processing

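Of the alternatives, fits within a slide and the filter on values above the floor on at least 1 array were chosen only after the results were seen. No named result that was called on either side changed direction without 1 array, with another floor, within 1 slide or in the total signal per miRNA. The other filters, only the 2 groups compared, and trended and robust moderation cannot move a difference between groups. They change only its SE and the calls. Over 2426 fits of 152 named results without 1 array, 2272 kept their side of the threshold, 144 lost the call and 10 gained one. Trended and robust moderation left all 152 on their side, the slide block 147, the replicate block 142, the mean of all probes 141, only the 2 groups 141, the lower floor 140, the total signal per miRNA 132, the missing filter 130 and the higher floor 113. The median of detected probes kept 136 on their side, quantile normalisation 122, normexp correction 112, the percentile of all probes 97, no scaling 68 and the authors' values 92. The filter on values above the floor kept all 152. The filter on detection on all 16 arrays gave a value for 96 of them, all on the same side; within slide 1 there were 150 values, of which 94 kept their side, and within slide 2 there were 152, of which 105 did. A reversal is counted only when the miRNA was called in the main model or under the alternative. Signal over background limits the dim miRNAs: 11, 21 and 24 tested miRNAs sat at the floor on all 8 arrays in the comparisons of BMMC with progenitors, MMC with BMMC and IgE_BMMC with BMMC. The replicate block gave 48 calls for MMC against IgE_BMMC, where lower calls went from 22 to 17. A scan block was not run, since the 2 scan times are the 2 slides.

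The counts of called miRNAs ranged without 1 array from 129 to 151 for BMMC against progenitors (144 in the main model), from 34 to 64 for MMC against BMMC (43), from 33 to 66 for IgE_BMMC against BMMC (53) and from 45 to 95 for MMC against IgE_BMMC (54); the lowest came without BMMC replicate 2, BMMC replicate 1, BMMC replicate 2 and MMC replicate 4, and each highest without progenitor replicate 4. The counts that moved by more than 1.5 times are these. BMMC against progenitors gave 84 with detection on all 16 arrays, where fewer miRNAs were tested, and 69 with the 2-fold limit. MMC against BMMC gave 22 under the percentile of all probes, 150 without scaling, 78 under the median of detected probes, 153 under normexp correction, 10 in the value table, 67 with only the 2 groups, 7 on slide 1, 24 on slide 2 and 5 with the 2-fold limit. IgE_BMMC against BMMC gave 196 without scaling, 168 under normexp correction, 26 in the value table, 30 without a filter, 22 on slide 1, 18 on slide 2 and 7 with the 2-fold limit. MMC against IgE_BMMC gave 157 without scaling, 115 under the median of detected probes, 132 under normexp correction, 33 in the value table, 28 with detection on all 16 arrays, 30 with the higher floor, 18 on slide 1 and 27 with the 2-fold limit. Each slide holds fewer arrays and the 2-fold limit can only remove calls. Scaling by 1 factor per array, or by none, moves all differences above the floor together. Elsewhere the cause was not tested. The differences in miRNAs detected per array ranged without 1 array from 36.9 to 50.25, -36.6 to -28, -62.5 to -54.5 and 22.2 to 29.2 in the same order, and by the software's own detection call they were 43.5, -38, -66.5 and 28.5. Without BMMC replicate 2 the difference of -28 had an adjusted p of 0.0571 in the exact permutation test. The groups still did not overlap then (BMMC 200 to 213, MMC 171 to 192), and fewer arrangements were left. Lists called by camera numbered 2, 1, 4 and 1 in that order; an estimated correlation gave 0 of 14, 13, 13 and 13 tested, fry 10, 5, 7 and 5, and the replicate block 2, 2, 4 and 1. Fry tests whether a list's members move, on balance, one way and does not compare them with other miRNAs.

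Scaling by the percentile of all miRNA probes reversed 12 of 152 named results, log2 values as follows. It changes only the 1 factor per array and the floor. Above the floor it thus moves every difference of a comparison by the same amount and tests no single miRNA. For BMMC against progenitors it gave 0.72 for let-7c-2*, 0.46 for miR-142-3p, 1.32 for miR-150, 0.18 for miR-15b*, 0.71 for miR-212, 0.69 for miR-219, 1.06 for miR-221, 0.60 for miR-222, 0.28 for miR-486 and 0.31 for miR-720. In MMC against BMMC the values became -0.00015 for miR-23b and -0.051 for miR-24. Quantile normalisation reversed 7, and the cause was not tested. It put BMMC against progenitors at 0.12 for let-7c-2*, 0.86 for miR-150, 0.65 for miR-219 and 0.47 for miR-486. It moved MMC against BMMC to -0.26 for miR-142-3p. Likewise IgE_BMMC against BMMC came to -0.26 for miR-142-3p and -0.28 for miR-720. The median of the probes detected on all arrays also changes only the 1 factor per array and the floor. Under it 1 result reversed: BMMC against progenitors gave 0.12 for miR-221. The authors' value table reversed 7, and the cause was not tested: BMMC against progenitors gave 0.26 for let-7c-2*, 0.83 for miR-150, 0.16 for miR-212, 1.83 for miR-219, 0.48 for miR-221, 0.020 for miR-222 and 0.44 for miR-486. The mean of all probes reversed 1, BMMC against progenitors, with -0.38 for miR-762, whose second probes point the other way.

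Without scaling 66 of the 152 reversed; by construction this alternative leaves the brightness of whole arrays in the values. For BMMC against progenitors it gave 1.18 for let-7c-2*, 0.40 for mghv-miR-M1-2, 0.93 for miR-142-3p, 1.79 for miR-150, 0.44 for miR-155, 0.64 for miR-15b*, 0.21 for miR-181b, 1.17 for miR-212, 1.55 for miR-219, 1.52 for miR-221, 1.06 for miR-222, 0.30 for miR-370, 0.94 for miR-486 and 0.77 for miR-720. In MMC against BMMC the values became -0.21 for miR-125a-3p, -0.49 for miR-142-3p, -0.62 for miR-155, -0.50 for miR-17*, -0.74 for miR-221, -0.94 for miR-222, -0.64 for miR-23b, -0.69 for miR-24, -0.26 for miR-24-1*, -0.19 for miR-24-2*, -0.41 for miR-29a*, -0.018 for miR-370, -0.21 for miR-671-5p, -0.16 for miR-718, -0.21 for miR-762 and -0.31 for miR-770-3p. The comparison of IgE_BMMC against BMMC turned to -0.55 for mghv-miR-M1-2, -1.43 for miR-142-3p, -1.55 for miR-146a, -1.80 for miR-146b, -1.73 for miR-155, -1.30 for miR-17*, -0.26 for miR-21*, -1.02 for miR-21, -1.47 for miR-212, -1.31 for miR-22, -1.69 for miR-221, -1.58 for miR-222, -1.76 for miR-223, -1.53 for miR-23b, -1.54 for miR-24, -0.75 for miR-24-1*, -0.79 for miR-24-2*, -1.30 for miR-29a*, -1.60 for miR-30c, -1.72 for miR-30d, -1.30 for miR-326, -1.32 for miR-340-3p, -1.75 for miR-374, -1.62 for miR-720 and -1.39 for miR-805. Values for MMC against IgE_BMMC were then 0.69 for let-7c, 0.44 for mghv-miR-M1-2, 0.024 for miR-146a, 0.59 for miR-146b, 0.96 for miR-221, 0.64 for miR-222, 0.49 for miR-24-1*, 0.28 for miR-326, 0.022 for miR-365, 0.54 for miR-720 and 0.66 for miR-93.

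Normexp correction reversed 21; its offset is added before scaling and so by construction lifts dim probes on dim arrays. For BMMC against progenitors it gave -1.27 for miR-132, -1.35 for miR-152, -0.089 for miR-33, -1.12 for miR-452 and -1.26 for miR-762. In MMC against BMMC the values became 0.52 for miR-128, 0.59 for miR-132, 0.51 for miR-146a, 0.34 for miR-150 and 0.029 for miR-425. The comparison of IgE_BMMC against BMMC turned to 0.66 for miR-125a-3p, 1.26 for miR-152, 0.24 for miR-290-5p, 0.95 for miR-292-5p and 0.98 for miR-452. Values for MMC against IgE_BMMC were then -0.32 for miR-134, -0.34 for miR-155, -0.13 for miR-292-5p, -0.13 for miR-370, -0.28 for miR-762 and -0.44 for miR-770-3p.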

Other observations

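Of the tests in this part, only the counts over other splits of the arrays were chosen before the results were seen; those of passenger arms and of other blood cells were chosen after.

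Passenger arms of hairpins, such as miR-24-1*, miR-24-2*, miR-21* and miR-29a*, were among the larger rises after IgE. Over 18 pairs of a passenger and its guide arm, the passenger's log2 change was higher by a median of 0.23, in 13 of 18 pairs (sign-flip permutation p = 0.0454, adjusted p = 0.182 over the 4 comparisons). Recent transcription of the hairpins could raise short-lived passengers first, but the adjusted value misses the threshold. An upward drift of dim probes on dim arrays was tested by matching each passenger to guides of a like level, which left a median of 0.31 (permutation p = 0.0372, adjusted p = 0.149). Both explanations stay open, the more so as the star in a name does not always mark the passenger; the same median was 0.20 in MMC against BMMC, with 12 of 19 pairs higher (p = 0.382 by permutation).

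Several miRNAs known from other blood cells were brighter in the progenitors, which were enriched for c-kit by magnetic separation. A lower share of the mast cell lineage would put all lists of other cell types lower in BMMC. Among lists with at least 3 tested members the highest median was 0.11 for the myeloid list (SD of its members 1.36, 5 up and 5 down), with -0.39 for the erythroid and megakaryocytic and -0.47 for the lymphoid list. The stromal list, with 2 members, lay above 0 (0.31 and 0.34), though miR-152 was above background on 0 progenitor arrays, and the test decides nothing. Erythroid precursors could have carried miR-451, which was well above background on 4 progenitor arrays, but miR-144 and miR-486 were so on 0 of them. The dim progenitor arrays keep that possibility open too, and the change of the lineage itself with culture was not separated from it.

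Chance assignment of arrays to groups was examined by splitting the 8 arrays of each comparison in all 35 ways into 4 and 4. In each comparison only 1 split, the real one, gave as many calls as were found, the smallest share that 35 splits can give. A random assignment of the arrays is thus an unlikely source of these counts. A mixed split also puts the group difference into the spread, which lowers its calls. The splits cannot separate the cells from the brightness of whole arrays, which also differed between groups. The real counts were 144 for BMMC against progenitors, 43 for MMC against BMMC, 53 for IgE_BMMC against BMMC and 54 for MMC against IgE_BMMC, and the highest among the other splits were 16, 0, 5 and 1. A split by slide gave 0 calls by limma in each comparison.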
